A study of Mus musculus with 17 samples.

How the data were processed

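Gene expression was measured by RNA sequencing in 17 mouse libraries made from KPC pancreatic tumour material. Per the labels' protocols, RNA was extracted with Trizol, enriched for poly-A RNA and made into libraries with the Illumina TruSeq RNA kit. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.0.4 and the mouse genome build mm9 were used. The authors deposited a table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments), 1 column per library and 1 line per gene, and this unit was read from the table's name and its values. The tool that computed FPKM and the gene annotation are not given in the sources used here, and no read counts were used here.

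The table held 23699 lines. The 248 symbols that stood on several lines were each represented by the line with the highest mean, which dropped 464 lines and left 23235 genes. In the table, 25 symbols had been turned into dates by spreadsheet software and were left as they stood. Loci under 100 bp long took 649 lines, all at 0 in the 17 libraries, and of the 810 loci under 300 bp only 65 had a value above 0. FPKM of such short loci is large for very few reads. Coordinates are those of the table, on mm9, and whether their start counts from 0 or 1 was not given.

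Sequencing depth was not stated. FPKM sums ran from 436257 to 529153 per library, and 11706 to 13654 lines reached 1 FPKM. Relative depth was estimated from values of up to 0.3 FPKM, since the ratio of the same gene in 2 libraries is a ratio of small whole numbers where whole reads were counted. With the best depth ratio, 47.3% to 56.1% of these ratios lay within 0.03 log2 units of a ratio of whole numbers up to 6, against 20.3% to 28.5% after random jitter. The values were thus only partly stepped and reads were not recovered. The resulting depths ran from 0.874 to 1.492 times that of PBS mouse 6, a 1.707-fold range. Without absolute counts, no counting interval or detection limit was computed. RNA integrity numbers in the labels ran from 7.4 (PBS mouse 5) to 10. In the grafts they ran from 8.6 to 9.2 with pre-treatment and from 9.3 to 10 without, so RNA quality and pre-treatment cannot be told apart there.

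Groups came from the sample titles. Tumours of mice 1 to 3 (decitabine) and 4 to 6 (PBS) came from different animals. The labels give each of the numbers 7 to 10 to 1 graft of pre-treated and 1 graft of untreated cells, and these were paired only in the alternative fits with the mouse as a block. The main graft fit did not use the pairs. Whether the number names the host of both grafts or the donor of their cells is not stated. The correlations of the paired deviations from their group means were 0.354, 0.0835, 0.0451 and 0.342 for mice 7, 8, 9 and 10. Among the untreated grafts, the pre-treated grafts of mice 7 and 10 correlated best with that of their own number, but that of mouse 8 with mouse 9 and that of mouse 9 with mouse 10. Whether the injected cells of different mice came from separate cultures is not stated, so the p-values for grafts measure the spread between grafts, which may partly be that of injection and host. Pearson's r of log2 values over genes between libraries of 1 group lay between 0.878 and 0.985, and 0 pairs of libraries were identical. Some pairs across groups were closer than any pair of 1 group in the same model. PBS mouse 6 and decitabine mouse 2 had 0.954, where in vivo pairs of 1 group reached 0.937. The 2 grafts of mouse 10 had 0.989, where graft pairs of 1 group reached 0.985. The cultured cells came from mouse 11, with 1 library per dose.

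Values were tested as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes moderation with a mean trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Every fold change is on that scale, which understates changes of genes near 0. Genes entered a fit with at least 1 FPKM in at least 3 libraries for the in vivo tumours and for the test of the difference between models, and in at least 4 for the grafts. The in vivo tumours and the grafts were fitted separately. Their difference was an interaction contrast over the 14 tumour libraries. In culture, with 1 library per dose, no test was run, and a gene was called higher or lower at a log2 ratio of at least 1, or at most -1, in the same direction at both doses, with at least 1 FPKM in any of the 3 libraries. Chance agreement of the doses, which shared the control library, was simulated 100 times from the spread of the untreated grafts.

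Gene groups came from 30 lists of pathway members and cell type markers, and 716 of their 720 entries were found in the table. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. A list's mean over its members was also compared between groups with an exact two-sided permutation test, which cannot give a p under 0.1 for 3 against 3 mice. In culture, a list's median ratio was placed among 10000 random lists of the same size and expression. Genes of a random list need not vary together as those of a real list may, so the percentiles are no p-values. The lists, tests, filters and most alternatives were fixed before the data were examined, as was the rule for naming genes. That rule took up to 12 passing genes in each direction of each tumour comparison and, where fewer than 3 passed, the 6 with the smallest unadjusted p. It also took up to 4 members of each described list, the 15 genes most raised and 10 most lowered in culture, and 16 genes named in advance, such as Dnmt1, Arg1, Irf7 and Dazl. Genes outside the rule were chosen after their values were seen: Ins1, Gcg and Ppy beside the acinar genes, the genes that differed between doses, and 5 germline genes of the closing observations.

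The pipeline was tested on simulated tables that kept the real genes' means and spread, with 200 genes changed by known folds. It was first run on simulated data only after a first run on the real table. For the in vivo design (13340 genes), 11% of 2-fold and 60% of 4-fold changes were recovered, with 74 genes called and 3 of them false. For the graft design (12882 genes) these were 82% and 92%, with 198 called and 12 false. For the difference between models (13721 genes) they were 31% and 76%, with 112 called and 5 false. Of 20 unchanged gene sets per design, 0, 0 and 1 passed 0.05. The simulated genes varied independently of each other, so this check does not cover lists whose members vary together. The estimated inter-gene correlation was 0.45 for the interferon list in vivo and 0.95 for the MHC class I list in grafts. Alternatives covered the pseudocount, the filter on low values, scaling, library weights, robust moderation, the mouse as a block, a joint fit, an acinar covariate, the correlation in camera, the thresholds in culture and leaving out each library in turn. Figures and depth estimates were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.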

Results

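The study measured how decitabine, a cytidine analogue that inhibits DNA methyltransferases, altered transcripts of KPC mouse pancreatic cancer in 3 settings. KPC mice carry mutant Kras and Trp53 in the pancreas and develop ductal tumours. Whole tumours from the head of the pancreas were taken from 3 mice given decitabine (1 uM by the label, 3 times every 48 h) and 3 given PBS. Subcutaneous grafts in syngeneic hosts were taken after 1 month, 4 of cells treated with 1 uM decitabine on 3 consecutive days before injection and 4 of untreated cells, and the labels give 1 mouse number to each pair. Cultured tumour cells of 1 mouse were left untreated or treated with 5 or 10 uM for 3 consecutive days, 1 library each. Expression was given as FPKM. Absolute depth was unknown, and relative depth varied 1.707-fold between libraries.

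Whole tumours of treated and untreated mice were compared first. Chi3l3 (Ym1), a chitinase-like protein of alternatively activated macrophages, stood at 754.8 ± 302.4 FPKM (SD, n = 3) in decitabine tumours and 44.1 ± 25.1 (n = 3) in PBS tumours, a log2 difference of 4.13 (SE 0.49). Arg1, the arginase of such macrophages, stood at 261.9 ± 126.2 against 101.2 ± 17.3. The eosinophil-associated ribonuclease genes Ear11 (log2 difference 2.26) and Ear6 (2.31), the chitinase-like Chi3l4 (2.49), the Fc receptor gene Fcgr4 (1.27) and Wnt4 (2.16) were also higher in each decitabine tumour than in any PBS tumour. Igf2bp3, an oncofetal RNA-binding protein, stood at 0.389 ± 0.077 against 4.17 ± 0.387 FPKM (log2 difference -2.39, SE 0.26), and Stbd1, a glycogen-binding protein, at 2.10 ± 0.796 against 9.60 ± 1.27. None of these genes passed correction: limma called 0 of 13498 genes, and 320 had an unadjusted p under 0.05 (260 higher, 60 lower) where 675 were expected by chance. The smallest adjusted p was 0.539, for Chi3l3 (chromosome 3, 105950471 to 105970482) and Igf2bp3 (chromosome 6, 49035216 to 49164953). When the 14 in vivo and graft libraries were fitted together, Igf2bp3 (adjusted p = 1.56e-06) and Stbd1 (adjusted p = 0.00826) passed. That fit shares 1 estimate of the spread with the grafts, so its p-values do not measure the spread between the in vivo mice alone. In it, 1246 genes had an unadjusted p under 0.05 for the in vivo difference, against 320 in the separate fit.

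Interferon response genes were higher as a group in the decitabine tumours by camera with its preset correlation (adjusted p = 9.33e-26), but not with an estimated one (adjusted p = 0.721 with an estimated correlation). Of the 40 measured, 38 had a positive log2 difference, with a median of 0.87, and 25 had an unadjusted p under 0.05. Adjusted over the list alone 14 passed, and 0 passed over all genes tested. Rtp4 stood at 11.8 ± 2.54 against 5.00 ± 0.397 FPKM, Parp9 at 19.5 ± 0.746 against 10.4 ± 2.01, Oas1g at 6.12 ± 2.92 against 1.64 ± 0.356 and Ifi35 at 27.4 ± 2.64 against 16.5 ± 2.21. Irf7, the transcription factor that amplifies the type I interferon response, stood at 28.1 ± 19.2 against 8.76 ± 0.617. The exact permutation p of the list mean was 0.1, the smallest that 3 against 3 mice allow. Adjusted over the lists it was 0.933, and no list had a lower adjusted value. The unadjusted permutation p was also 0.1 for adipocyte genes, 0.2 for T cell genes and 0.3 to 0.8 for the other lists called in vivo. MHC class I genes, with Tapbp (log2 difference 0.42) and Psmb10 (0.43) among them, were positive in 14 of 14 members with a median of 0.23 and passed (adjusted p = 0.00864; adjusted p = 0.721 with an estimated correlation). That call was lost without decitabine mouse 1 (adjusted p = 0.51), without decitabine mouse 2 (0.149), without PBS mouse 5 (0.217), without both of the latter (0.748) and with the acinar level as a covariate (0.453).

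**Figure D1:**
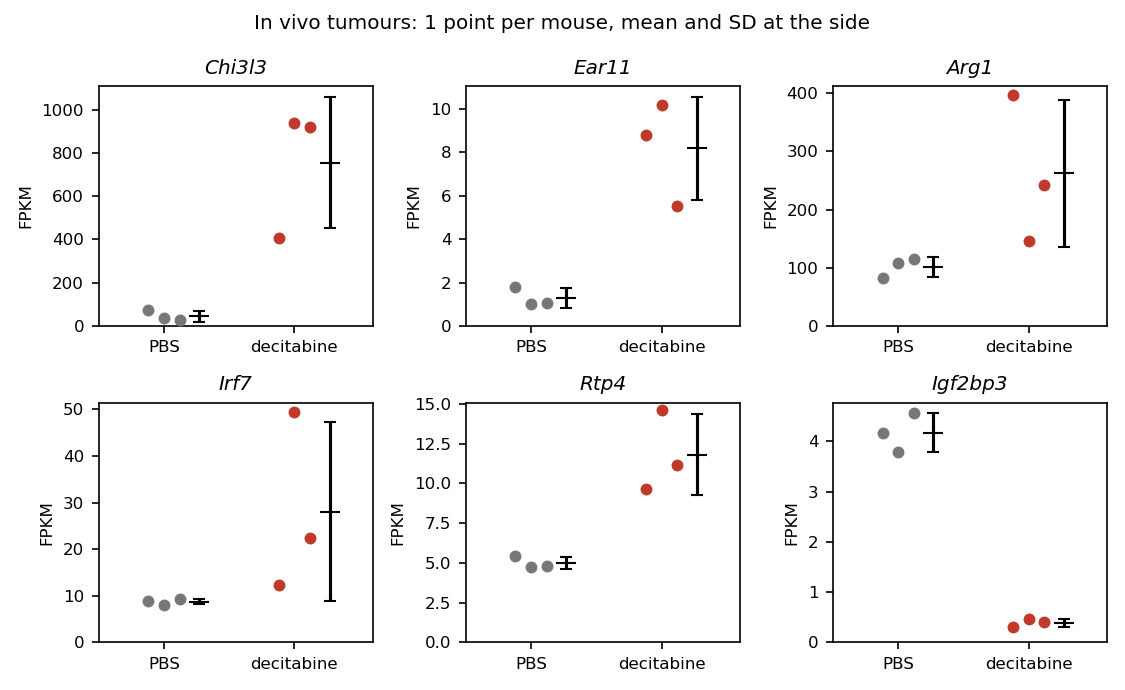
FPKM of 6 genes in whole tumours of mice given PBS (grey) or decitabine (red), 1 point per mouse, with the mean and SD as a bar at the side and axes that start at 0. Chi3l3 lay between 405.8 and 936.9 in decitabine tumours and between 25.1 and 72.6 in PBS tumours, whereas Igf2bp3 lay at most at 0.457 and at least at 3.79.

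T cell, acinar and heat shock transcripts were lower as groups in the decitabine tumours by camera with its preset correlation, and none of the 3 calls held with an estimated one. T cell genes were negative in 18 of 20 members (median -0.75; adjusted p = 9.25e-17, or adjusted p = 0.721 with an estimated correlation), with Cd3d at 1.54 ± 0.80 against 3.69 ± 1.00 FPKM, Lck at 2.85 ± 1.16 against 5.57 ± 1.29 and Cd8b1 at 1.13 ± 0.934 against 3.02 ± 0.895. Acinar enzyme genes were negative in 26 of 28 (median -3.51; adjusted p = 7.13e-21, or adjusted p = 0.721 with an estimated correlation), with SDs larger than the means: Prss2, a trypsinogen, stood at 194.2 ± 304.2 against 2302 ± 3198. Immediate early and heat shock genes were negative in 19 of 23 (median -0.24; adjusted p = 1.06e-05, or adjusted p = 0.721 with an estimated correlation), with Hsp90aa1 at 93.0 ± 18.5 against 144.2 ± 21.1. Of the 14 lists called among 28, only these 3 and the interferon list kept their call and direction whichever library was left out. PBS mouse 5, whose RNA integrity number of 7.4 was the lowest, had the highest acinar median (1262 FPKM), and decitabine mouse 1 the lowest (0.765 FPKM).

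The calls of the other 9 lists each depended on particular libraries, and those of the endothelial, islet and chemokine lists also on the scaling. B and plasma cell genes were negative in 13 of 17 members (median -0.92; adjusted p = 7.15e-08, or adjusted p = 0.721 with an estimated correlation), with Ms4a1 at 2.67 ± 1.58 against 8.63 ± 4.99 FPKM. The B and plasma cell call was lost without decitabine mouse 3 (adjusted p = 0.106). MHC class II genes were negative in 10 of 10 members (median -0.71; adjusted p = 1.51e-04, or adjusted p = 0.721 with an estimated correlation). The MHC class II list turned to higher without that mouse (adjusted p = 0.71). Proliferation genes were negative in 27 of 32 members (median -0.16; adjusted p = 4.12e-05, or adjusted p = 0.721 with an estimated correlation). The proliferation call was lost without decitabine mouse 2 (0.359), PBS mouse 4 (0.377) or both decitabine mouse 2 and PBS mouse 5 (0.714). Fibroblast genes were negative in 24 of 30 members (median -0.33; adjusted p = 1.51e-04, or adjusted p = 0.721 with an estimated correlation). The fibroblast call was lost without decitabine mouse 2 (0.101) or 3 (0.106) and turned to higher without PBS mouse 4 (0.739). Endothelial genes were negative in 18 of 20 members (median -0.22; adjusted p = 0.0138, or adjusted p = 0.721 with an estimated correlation). The endothelial list turned to higher without decitabine mouse 3 (0.898) or PBS mouse 4 (0.377), and lost the call with TMM-style scaling (0.0504), quantile normalization (0.0972) or library weights (0.909). Islet genes were negative in 11 of 13 members (median -0.65; adjusted p = 0.0267, or adjusted p = 0.721 with an estimated correlation). The islet call was lost without decitabine mouse 2 (0.065), PBS mouse 5 (0.309) or PBS mouse 6 (0.208) and turned without decitabine mouse 3 (0.224). It was also lost with TMM-style scaling (0.146), quantile normalization (0.128), no filter on low values (0.143) or without decitabine mouse 2 and PBS mouse 5 together (0.36). Chemokine genes were negative in 15 of 28 members (median -0.10; adjusted p = 0.0267, or adjusted p = 0.721 with an estimated correlation), with Ccl5 at 8.56 ± 3.67 against 16.5 ± 2.27. The chemokine call was lost without decitabine mouse 2 (0.065) or 3 (0.71), or PBS mouse 4 (0.0902) or 6 (0.271), and with TMM-style scaling (0.135), quantile normalization (0.102) or no filter on low values (0.0559). Adipocyte genes were positive in 12 of 14 members (median 0.45; adjusted p = 0.00395, or adjusted p = 0.721 with an estimated correlation), with the adipsin gene Cfd at 34.4 ± 17.2 against 12.2 ± 1.59. The adipocyte call was lost without decitabine mouse 2 (0.248), PBS mouse 6 (0.16) or both decitabine mouse 2 and PBS mouse 5 (0.361). Hepatocyte and intestine genes were positive in 12 of 14 members (median 1.048; adjusted p = 0.00721, or adjusted p = 0.721 with an estimated correlation), with Apoa4 at 126.2 ± 211.9 against 1.29 ± 2.09. The hepatocyte and intestine call was lost without decitabine mouse 2 (0.0677), PBS mouse 4 (0.378) or PBS mouse 6 (0.208). Decitabine mouse 2 was the library with intestinal transcripts.

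The lists of alternative macrophage activation (14 of 25 positive, adjusted p = 0.262), macrophages (adjusted p = 0.178), neutrophils (0.965), immune checkpoints (0.0898), ductal tumour genes (0.0676, but 0.0107 with TMM-style scaling and 0.00417 with quantile normalization, both higher), p53 targets (0.24), imprinted genes (0.071) and the methylation machinery (0.401) did not pass in vivo. Without PBS mouse 4 the ductal list passed as lower (0.0104), but as higher without decitabine mouse 1 (0.00898), PBS mouse 5 (0.00479) or 6 (2.1e-05). Without decitabine mouse 1 macrophages (2.63e-05), neutrophils (4.23e-08), checkpoints (0.00109) and imprinted genes (0.00829) passed as lower. Without decitabine mouse 3 neutrophils (4.08e-04), alternative activation (0.00248) and p53 targets (0.0203) passed as higher, as did macrophages without PBS mouse 4 (0.026). The alternative activation list held 3 members that passed over the list alone (Chi3l3, Ear11 and Chi3l4). The median, mean and test differed in sign for the germline list (median 0.00, mean 0.10, test down), the neutrophil list (median -0.15, mean 0.06, test down), the imprinted list (median 0.00, mean -0.09, test down) and the methylation machinery (median 0.01, mean 0.02, test down). The T cell checkpoint receptor genes stood at 0.815 ± 0.559 against 2.89 ± 2.50 FPKM (Ctla4) and 0.86 ± 0.08 against 1.44 ± 0.42 (Pdcd1), and neither passed (adjusted p = 0.999 for each). Dnmt1, the maintenance methyltransferase targeted by the drug, stood at 18.7 ± 1.07 against 25.9 ± 7.34 (adjusted p = 0.999). Of other genes named in advance, Cd8a stood at 0.966 ± 0.787 against 1.77 ± 0.712, Cd4 at 2.57 ± 1.503 against 3.81 ± 0.647, Cd274 (PD-L1) at 7.31 ± 2.72 against 5.55 ± 1.82, Kras at 31.9 ± 4.98 against 32.4 ± 4.99, Trp53 at 38.7 ± 9.85 against 30.4 ± 19.8 and Cdkn1a at 56.0 ± 18.8 against 67.8 ± 24.5 (adjusted p = 0.999 for each).

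Grafts of pre-treated and untreated cells were compared next. In the 4 pre-treated grafts Ggh, the gamma-glutamyl hydrolase of folate metabolism, rose to 67.3 ± 7.63 from 39.4 ± 1.91 FPKM (SD, n = 4 each; log2 difference 0.76, SE 0.09, adjusted p = 0.0492; chromosome 4, 19969198 to 19993258). Ltbr, the lymphotoxin beta receptor, fell to 119.7 ± 5.85 from 171.2 ± 3.39 (log2 difference -0.52, SE 0.05, adjusted p = 0.0397; chromosome 6, 125256588 to 125263888). Mpst, a mercaptopyruvate sulfurtransferase, fell to 30.2 ± 0.535 from 42.2 ± 0.924 (log2 difference -0.47, SE 0.05, adjusted p = 0.0342; chromosome 15, 78237141 to 78244445). Snora3, a small nucleolar RNA, was listed at 104.1, 57.1, 50.1 and 51.0 FPKM in the pre-treated grafts of mice 7, 8, 9 and 10 and at 0 in the 4 untreated grafts (adjusted p = 5.01e-06). Its locus spans 120 bp (chromosome 7, 116663645 to 116663765), and its values in mice 7, 8, 9 and 10 were 1.14, 2.73, 2.74 and 3.75 times the smallest value that any locus of like span took in the same library. Multiplied by relative depth, these values were 1.88, 1.18, 1.06 and 1 times the smallest of them, so they may rest on very few reads. The untreated grafts had no spread for Snora3, so its p rests on the spread of the pre-treated grafts alone. With the mouse as a block, Snora3 alone passed (adjusted p = 0.00165), and Ggh (0.129), Ltbr (0.212) and Mpst (0.212) did not.

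These 4 genes of 12981 were all that limma called, but 2106 had an unadjusted p under 0.05 (633 higher, 1473 lower; 649 expected). Next in order were Serpinb6b, a serine protease inhibitor (log2 difference 0.60, adjusted p = 0.0797), the synaptic vesicle protein gene Synpr (1.32, 0.0797), the secreted protein gene Crisp1 (2.42, 0.105), Rgs17 (0.69, 0.108), the mitochondrial Pck2 (-0.59, 0.0663), the TNF receptor gene Tnfrsf1a (-0.44, 0.0663), the valyl-tRNA synthetase gene Vars (-0.40, 0.0797) and Large (-0.52, 0.0797). Chi3l3 stood at 667.2 ± 835.1 against 91.6 ± 83.4 FPKM and Arg1 at 228.0 ± 156.7 against 91.8 ± 46.7, with adjusted p of 0.485 and 0.438. Without any 1 of the untreated grafts only Snora3 passed, and without any 1 of the pre-treated grafts 0 genes did: Ggh, Ltbr and Mpst lost their calls in each of these fits, and Snora3 missed the filter in those without a pre-treated graft. Weighting libraries by their scatter in this fit, not by RNA integrity, gave 846 genes. Scaling with trimmed means gave 1, quantile normalization 2 and leaving out loci under 300 bp 0. RNA integrity was lower in each pre-treated graft than in any untreated graft. For the genes and lists of the grafts, RNA quality therefore cannot be told apart from pre-treatment.

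Antigen presentation genes were lower as groups in the grafts of pre-treated cells by camera with its preset correlation, but not with an estimated one nor without the pre-treated grafts of mice 7 and 9 together (adjusted p = 0.467 for MHC class I, MHC class II and dendritic genes). In the pair of mouse 8 the list means went the other way, at 6.56 with pre-treatment against 6.48 log2 units for MHC class I and 5.97 against 5.92 for MHC class II. MHC class I genes were negative in 15 of 15 members (median -0.66; adjusted p = 7.59e-04, or adjusted p = 0.715 with an estimated correlation), with H2-D1 at 535.8 ± 195.1 against 822.1 ± 145.7 FPKM. MHC class II genes were negative in 10 of 10 (median -0.68; adjusted p = 0.00291, or adjusted p = 0.715 with an estimated correlation), with Cd74 at 521.3 ± 271.9 against 793.2 ± 110.1, and dendritic cell genes in 18 of 18 (median -0.39; adjusted p = 0.00258, or adjusted p = 0.715 with an estimated correlation), with Xcr1 at 0.91 ± 0.771 against 2.02 ± 0.58. Proliferation genes were higher by little (25 of 32 positive, median 0.11; adjusted p = 3.14e-05, or adjusted p = 0.715 with an estimated correlation), with Top2a at 65.1 ± 5.42 against 53.1 ± 3.21 and Cdk1 at 44.1 ± 4.18 against 36.1 ± 1.59. Acinar genes were higher (8 of 8 positive, median 3.27, adjusted p = 3.69e-04, or adjusted p = 0.715 with an estimated correlation). Only these 8 of the 31 listed passed the filter in the grafts. Acinar genes were abundant only in the pre-treated grafts of mice 7 and 9. There the median over all 31 was 297.9 and 54.9 FPKM, against at most 0.418 in the other 6 grafts. These 5 lists kept their calls whichever library was left out. Without the pre-treated grafts of mice 7 and 9 together the proliferation (0.0644) and acinar lists (0.806) did not pass either, and the proliferation mean of the pair of mouse 8 was 4.47 log2 units with pre-treatment against 4.54. By the exact permutation test of list means, the smallest p of any graft list was 0.114 (acinar and dendritic genes), where 0.0286 was possible. The lowest permutation p adjusted over the lists was 0.771.

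**Figure D2:**
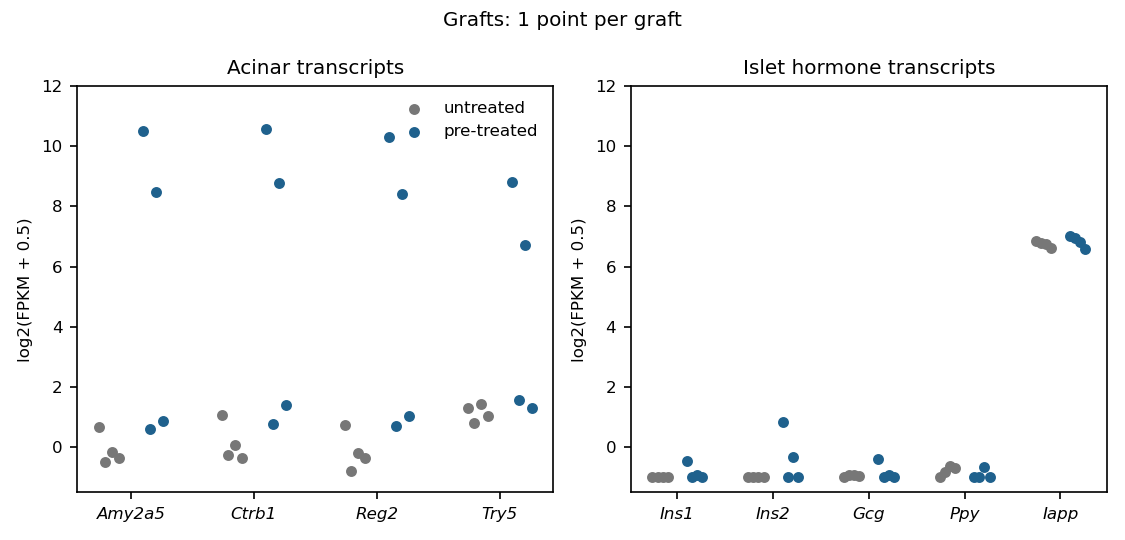
Acinar enzyme (left) and islet hormone (right) transcripts in grafts of untreated (grey) and pre-treated (blue) cells as log2(FPKM + 0.5), 1 point per graft. In 2 pre-treated grafts (mice 7 and 9) the acinar transcripts were abundant, whereas Ins1, Ins2, Gcg and Ppy reached at most 1.28 FPKM in any graft and Iapp averaged 115.3 FPKM with pre-treatment and 107.9 without.

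Of the other 7 lists called among 27 in the grafts, fibroblast genes were positive in 27 of 30 members (median 0.20; adjusted p = 3.69e-04, or adjusted p = 0.715 with an estimated correlation), with Tagln at 85.3 ± 19.3 against 51.1 ± 16.8 FPKM. The fibroblast call was lost without untreated graft 9 (adjusted p = 0.281) or with library weights (0.0618). Neutrophil genes were positive in 20 of 23 members (median 0.64; adjusted p = 0.00245, or adjusted p = 0.715 with an estimated correlation), with Mmp9 at 13.2 ± 7.47 against 4.67 ± 2.81. The neutrophil call was lost without pre-treated graft 7 (0.087). Macrophage genes were positive in 17 of 23 members (median 0.16; adjusted p = 0.014, or adjusted p = 0.715 with an estimated correlation). The macrophage call was lost without pre-treated graft 9 (0.265) or untreated graft 9 (0.357) and with quantile normalization (0.0718). Mesenchymal transition genes were positive in 13 of 15 members (median 0.13; adjusted p = 0.0308, or adjusted p = 0.715 with an estimated correlation). The mesenchymal transition call was lost without pre-treated graft 9 (0.0897) or 10 (0.0841) or untreated graft 9 (0.332), and with TMM-style scaling (0.066) or quantile normalization (0.0647). Interferon response genes were negative in 38 of 40 members (median -0.35; adjusted p = 0.00455, or adjusted p = 0.767 with an estimated correlation). The interferon call was lost without pre-treated graft 9 (0.123) or 10 (0.137) or untreated graft 9 (0.193). T cell genes were negative in 15 of 16 members (median -0.67; adjusted p = 0.00858, or adjusted p = 0.715 with an estimated correlation), with Lck at 2.73 ± 1.76 against 4.75 ± 1.20. The T cell call was lost without pre-treated graft 7 (0.0638) or 9 (0.0753) or untreated graft 9 (0.0663). Adipocyte genes were negative in 12 of 14 members (median -0.51; adjusted p = 0.0283, or adjusted p = 0.715 with an estimated correlation). The adipocyte call was lost without pre-treated graft 8 (0.129) or 10 (0.103) or untreated graft 7 (0.223). Without pre-treated grafts 7 and 9 together the interferon (0.763), macrophage (0.766) and mesenchymal transition lists (0.137) lost their calls, and the T cell (0.993) and neutrophil lists (0.806) turned. Skeletal muscle genes, from tissue that can lie next to a subcutaneous graft, were negative in 19 of 20 (median -0.90; adjusted p = 0.245), and with the mouse as a block they and mast cell and eosinophil genes passed (0.0228, down, and 0.0463, up). With an estimated correlation, in the fit without the block, camera gave these 2 lists an adjusted p of 0.918 and 0.715. The muscle list mean was higher with pre-treatment only in the pair of mouse 10 (4.99 against 3.82 log2 units).

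**Figure D3:**
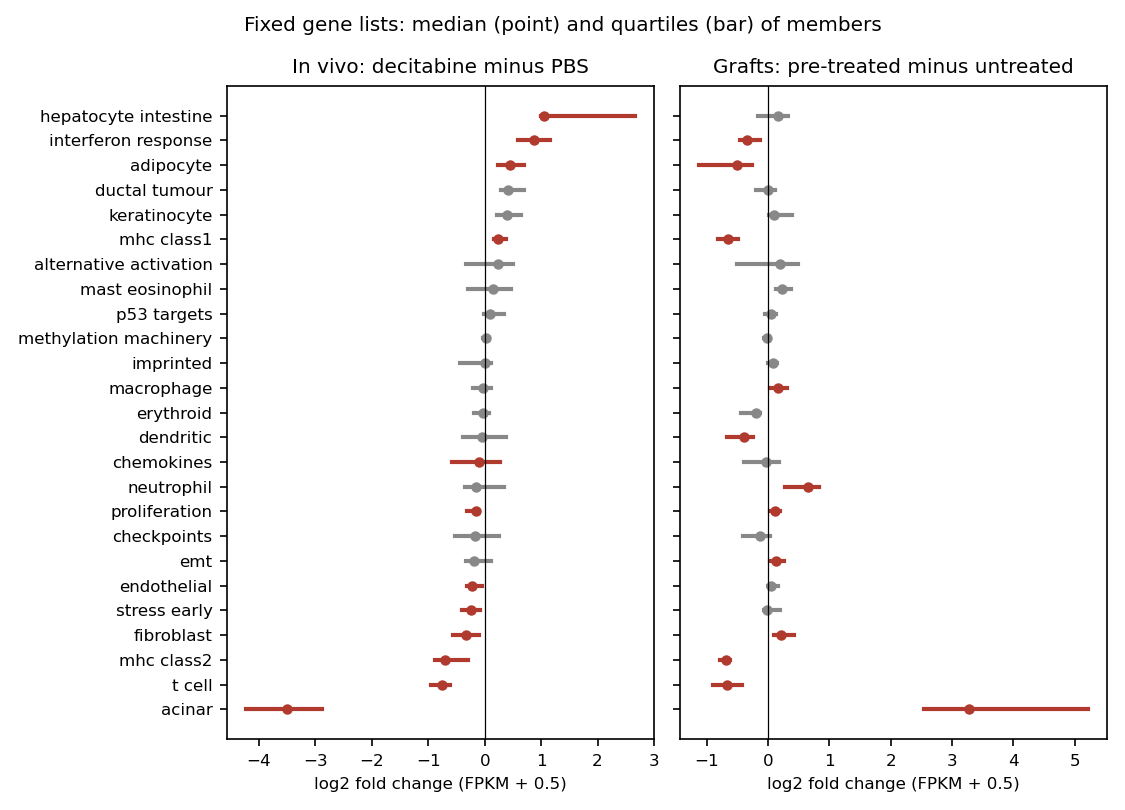
Median (point) and quartiles (bar) of members' log2 differences for the lists tested in both models, in whole tumours (left, decitabine minus PBS) and grafts (right, pre-treated minus untreated). Red marks an adjusted camera p under 0.05 with the preset correlation. The interferon list stood at 0.87 in vivo and -0.35 in grafts, and the acinar list at -3.51 (28 members measured) and 3.27 (8 measured).

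The models were then compared directly. Of 13982 genes, limma's interaction test called 2: Igf2bp3, whose in vivo difference was lower than that in grafts by 1.96 log2 units (log2 difference -1.96, SE 0.17, adjusted p = 2.56e-04), and Snora3, listed at 0 in all 6 in vivo tumours (log2 difference -6.98, adjusted p = 2.53e-07). Snora3 varied only within the pre-treated grafts, so its p does not measure a spread within the other groups. In the grafts Igf2bp3 was lower too, at 6.42 ± 0.464 against 8.80 ± 0.231 FPKM and in 4 of 4 pairs, without passing (log2 difference -0.43, adjusted p = 0.108). In cultured cells Igf2bp3 was not lower, at 1.27, 1.21 and 1.27 FPKM in control, 5 uM and 10 uM cells (1 library each). Without decitabine mouse 1, 2 or 3 the count of genes that the interaction test called was 9, 5 or 4. By camera on the same contrast, interferon response (median 1.29, adjusted p = 1.11e-19) and MHC class I genes (1.01, 1.55e-05) were higher in vivo relative to the grafts, and acinar (-7.09, 1.14e-26), B and plasma cell (-0.97, 1.89e-08), fibroblast (-0.62, 1.26e-07) and proliferation genes (-0.28, 1.64e-07) lower. With an estimated correlation the adjusted p was 0.675 for the interferon and acinar lists and 0.771 for the other 4. Of 12652 genes tested in both models, 42 had an unadjusted p under 0.05 in both. Of these, 15 were higher in both (11.8 expected for independent lists), 3 lower in both (5.28 expected: Igf2bp3, Stbd1 and the T cell kinase gene Lck) and 24 opposite (30.04 expected). Cda, the cytidine deaminase that inactivates decitabine, was among the 15, with log2 differences of 0.61 in vivo and 0.47 in grafts, and neither passed correction.

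In cultured tumour epithelial cells, 32 of 32 proliferation, 12 of 18 chemokine and 15 of 22 immediate early and heat shock genes stood higher with decitabine at both doses, and 19 of 24 ductal tumour genes lower. At least 2-fold at both doses, 17, 2 and 2 members of the first 3 lists were higher and 1 chemokine gene lower, while 1 ductal gene was lower and 1 higher. At both doses 203 genes were at least 2-fold higher and 110 at least 2-fold lower, of 11949. The chemokine genes Cxcl10 (3.72, 17.7 and 20.3 FPKM in control, 5 uM and 10 uM cells) and Ppbp (0.949, 6.63 and 8.55), the calcium-binding S100a7a (13.4, 58.4 and 81.6), Serpinb9b (6.61, 29.7 and 38.9), the stress factor Atf3 (11.1, 40.7 and 39.7), the p53 target Plk2 (17.1, 58.8 and 69.7), the growth factor gene Areg (2.84, 10.6 and 11.1) and smooth muscle actin Acta2 (4.26, 14.4 and 23.4) were among the most raised. The trefoil factor Tff3 (435.2, 106.0 and 78.7), the ketogenic enzyme Hmgcs2 (7.47, 1.49 and 1.25), haptoglobin Hp (18.8, 4.68 and 3.51) and the phosphate transporter Slc34a2 (5.47, 1.19 and 0.761) were among the most lowered. With 1 library per dose, these differences have no replicate check. Small RNA loci (Snora31, Snora28, Snora52 and Snora64 up, Mir365-2, Snora21, Snora7a and Snora16a down) also met the rule, most of them listed at 0 on one side.

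Proliferation genes were higher in 32 of 32 members at both doses, 17 of them at least 2-fold, with medians of 1.01 and 1.13 log2 units, above all 10000 matched random lists (percentile 100 at each dose). Rrm2, a ribonucleotide reductase subunit, went from 27.4 to 78.1 and 87.0 FPKM, Ccna2 from 29.1 to 68.3 and 72.0, and Aurka from 12.9 to 30.1 and 33.0. Dnmt1 went from 35.5 to 53.9 and 59.1 and its partner Uhrf1 from 11.2 to 25.6 and 29.3. Fibroblast (medians 0.41 and 0.51), mesenchymal transition (0.45 and 0.50), immediate early (0.34 and 0.43) and chemokine genes (0.34 and 0.50) lay at percentiles of at least 99.98. Interferon response genes (-0.23 and -0.30), with Mx1 from 14.6 to 6.86 and 5.21, MHC class I genes (-0.42 and -0.46), with Tap2 from 6.43 to 3.41 and 3.18, and ductal genes (-0.35 and -0.43), with Tff2 from 286.7 to 94.1 and 83.9 and Muc1 from 517.8 to 289.6 and 255.1, lay at percentiles of at most 0.01. So did hepatocyte and intestine genes (-0.79 and -0.98; percentile 0 at each dose), while p53 targets (0.08 and 0.07) lay at the percentiles 72.0 and 58.0. Dazl, a germline gene silenced by promoter methylation in somatic cells, stood at 0.012, 0.111 and 0.211 FPKM, under the floor of 1.

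**Figure D4:**
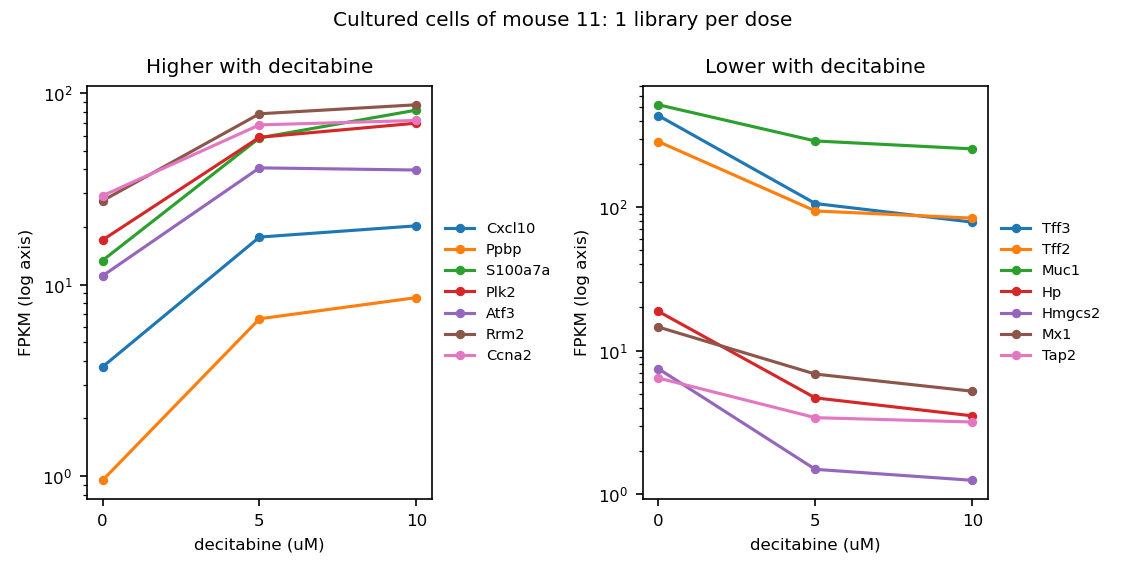
FPKM on a log axis against decitabine dose (uM) in cultured cells, 1 library per dose and no replicates, for genes higher (left) and lower (right) with the drug. Rrm2 went from 27.4 to 78.1 and 87.0 and Tff3 from 435.2 to 106.0 and 78.7, with most of each difference reached at 5 uM.

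At 5 uM 216 genes were at least 2-fold higher and 117 at least 2-fold lower than in the control, and at 10 uM 338 and 197. Of the 313 genes changed at both doses, 87.5% had the larger change at 10 uM. Between 5 and 10 uM, 10 genes were at least 2-fold higher and 6 at least 2-fold lower at the higher dose, of which Gvin1, Hist1h4m, Rpph1, Prl2c4 and Amd1 span over 300 bp and the other 11 are small RNA loci. Of the 203 genes raised at both doses and the 110 lowered, independent lists would share 6.11 and 1.93, and simulated libraries without an effect gave 0 and 0. The simulated noise followed the smoothed spread of the untreated grafts, without the jumps of small RNA loci or a control library that differs by itself. It therefore cannot tell an effect of the drug from an unusual control library. The correlation of log2 ratios over genes was 0.929, where the shared control alone gave 0.50. The covariance was 0.167 against a simulated 0.0176. Part of the agreement therefore comes from the shared control library.

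Genes raised by the drug in culture were also compared in the tumours. In the grafts of pre-treated cells, 166 of 189 measured were positive, with a median log2 difference of 0.18 (camera p = 4.71e-17; p = 0.0515 with an estimated correlation; p = 1.19e-17 with the mouse as a block), and 41 had an unadjusted p under 0.05 in that direction. In whole tumours, 133 of 186 were negative, with a median of -0.16 (p = 2.91e-07; p = 0.252 with an estimated correlation). The in vivo call was lost without decitabine mouse 2, where camera gave 0.0525, without PBS mouse 4, where it gave 0.156, and without PBS mouse 5 and decitabine mouse 2 together, where it gave 0.0793. Genes lowered in culture were lower in grafts (64 of 86 negative, median -0.24; p = 0.00556; p = 0.387 with an estimated correlation) and higher in whole tumours (77 of 94 positive, median 0.64; p = 3.96e-06; p = 0.292 with an estimated correlation).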

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

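The tests of islet hormones, of pre-treatment, of leukocyte markers, of the interferon list in culture, of depth and of germline genes in culture were chosen only after the results they bear on were seen, and the fit without PBS mouse 5 and decitabine mouse 2 was added after the data were seen.

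Acinar enzyme transcripts were abundant in 2 of the 8 grafts, both of pre-treated cells (mice 7 and 9), and the difference between models for this list was -7.09 (camera adjusted p = 1.14e-26; adjusted p = 0.675 with an estimated correlation). The ratio of islet hormone to acinar medians in these 2 grafts was at most 0.036 times the lowest among the in vivo tumours. The in vivo ratios ran from 0.0692 in PBS mouse 5, richest in acinar transcripts, to 217 in decitabine mouse 1. Normal pancreas was not measured, so this argues only against carried-over tissue with islets in the proportions of these tumours. RNA or reads from the library richest in acinar transcripts, PBS mouse 5, would have brought its other abundant transcripts, and 7 of these stood at a median of at most 0.0184 times the level needed. Pre-treatment of the cells stays open, since the chance that 2 of 8 grafts are both pre-treated ones is 0.214. With only 2 such grafts this test could not have fallen under 0.05. Acinar tissue with few or no islets, or acinar transcripts made by the tumour cells, may also account for it and neither was tested.

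Interferon response genes were higher in tumours of treated mice and differed between the models by a median of 1.29 (camera adjusted p = 1.11e-19; adjusted p = 0.675 with an estimated correlation). A larger share of leukocytes as a whole is argued against by 100 leukocyte markers, whose median log2 difference was -0.307 and whose upper quartile of 0.103 lay under the interferon list's lower quartile of 0.598. The list medians differed, at -0.75 for T cells and -0.03 for macrophages, so a change in the kinds of leukocytes was not tested. PBS mouse 5 had the lowest RNA integrity, and decitabine mouse 2 was the library with intestinal transcripts. Decitabine mouse 2 also had the highest interferon list mean, at 3.99 log2 units against 3.36 and 3.12 in decitabine mice 1 and 3. Without decitabine mouse 2 alone the interferon list's median fell from 0.87 to 0.60, with 37 of 39 members above 0. Without PBS mouse 5 and decitabine mouse 2 it was 0.61 with 35 of 39 members above 0, so these libraries were not the whole source. In cultured cells at 5 or 10 uM the list's median was at most -0.233, so no direct rise was seen there. Both doses had 1 library and shared 1 control, so an unusual control library cannot be told apart from the drug. A response at 1 uM or one that needs the animal was not tested. A response of the whole tumour to the drug remains a hypothesis, as do other differences between the 6 animals, which could not be separated from treatment with 3 mice per group.

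In culture 6343 symbols were listed at 0 in the control, 5502 at 5 uM and 5389 at 10 uM. Greater depth is argued against by the estimated depths, at most 1.02 times that of the control. Of the olfactory receptor genes at 0 in the control, 8.26% came up, against 39.4% of other genes (Fisher's exact p = 2.23e-100), which meets the bound set beforehand against stray reads; that bound was a poor one, since olfactory genes above 0 themselves went from 53 to 80 and 92 of 1118, so stray reads stay open. Germline genes came up in 13 of 26 cases (50%) against 33.6% of other genes (Fisher's exact p = 0.0951), so loss of methylation at such genes may contribute but was not shown. Values under 0.001 FPKM were counted as 0, a tolerance added after a first look, which changed none of these readings.

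By the interaction test of limma, Igf2bp3 (log2 difference -1.965, adjusted p = 2.56e-04) and Snora3 (-6.976, adjusted p = 2.53e-07) differed between the models. For Snora3 that p rests on the spread of the pre-treated grafts alone. Further lists differed with the preset correlation, as median difference, adjusted p and adjusted p with an estimated correlation: MHC class I (1.01, 1.55e-05, 0.771), imprinted (-0.28, 0.0389, 0.771), T cell (-0.17, 0.0368, 0.86), B and plasma cell (-0.97, 1.89e-08, 0.771), macrophage (-0.0838, 0.02, 0.86), neutrophil (-0.26, 0.00704, 0.86) and fibroblast genes (-0.62, 1.26e-07, 0.771). The same held for endothelial (-0.29, 0.00511, 0.777), islet (-0.74, 0.0206, 0.777), proliferation (-0.28, 1.64e-07, 0.771), mesenchymal transition (-0.33, 0.0113, 0.777), adipocyte (0.67, 0.00447, 0.771), immediate early and heat shock (-0.27, 4.17e-05, 0.771) and hepatocyte and intestine genes (1.34, 0.0269, 0.777). Genes raised in culture differed by -0.32 (p = 1.74e-16; p = 0.0534 with an estimated correlation) and genes lowered in culture by 0.90 (p = 1.94e-05; p = 0.263 with an estimated correlation).

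Single grafts stood far from the other 3 of their group in 12 of 116 Dixon tests, where chance gives about 1 in 20 (5.8). The gap over the range was 0.921 for the germline, 0.882 for the mast cell and eosinophil, 0.978 for the keratinocyte and 0.886 for the erythroid list in pre-treated graft 8, and 0.91 for the adipocyte list in pre-treated graft 9. It was 0.913 for the neutrophil, 0.908 for the keratinocyte and 0.947 for the erythroid list in untreated graft 7. In untreated graft 9 it was 0.839 for the fibroblast, 0.885 for the endothelial and 0.935 for the mesenchymal transition list, and in untreated graft 8 it was 0.876 for Dnmt3b.

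Other splits of the same libraries were fitted. The 10 splits of the in vivo tumours are too few for a share under 0.05: the real split called 0 genes (highest other 5; 10 of 10 as many), 14 lists (19; 8 of 10) and the culture-raised genes with a camera value of 2.91e-07 (7.78e-20; 5 of 10). Of the 35 splits of the grafts, 3 called at least the real 4 genes (highest other 70), 2 gave at least the real 2106 genes at an unadjusted p under 0.05 (2351), 19 called at least the real 12 lists (20) and 4 gave the culture-raised genes a p as small (lowest other 2.93e-19), so chance is not excluded for any of them. Among the 8 splits that, like the real one, part all pairs, 1, 1, 5 and 3 did so, with 1 gene, 873 genes, 16 lists and 2.93e-19 as the highest of the others. For the difference between models, 37 of 100 arrangements drawn from 700 called at least the real 2 genes (389). Splits that call 70 or 389 genes point to structure among these samples apart from treatment. The other splits called a median of 16 lists in vivo and 12 in grafts, so the real splits did not call more lists than a typical other split.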

How the results depend on the processing

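The settings without short loci, without PBS mouse 5 and decitabine mouse 2, without pre-treated grafts 7 and 9 and without proliferation members were chosen after seeing the data. Where a value moved, the cause was not tested unless named.

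For in vivo genes limma called 0 in each setting except 1 fit over 14 libraries, which called 2 (Igf2bp3, Stbd1), and 0 whichever library was left out. Igf2bp3 missed the filter in the fits without a PBS mouse, so it was not tested in those. In vivo lists numbered 14, from 7 to 22 with single libraries left out, and 0 with an estimated correlation. The culture-raised genes in vivo had p from 2.42e-13 to 0.156 with single libraries left out, 0.0793 without PBS mouse 5 and decitabine mouse 2 and 0.252 with an estimated correlation.

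The 4 graft genes became 1 with TMM-style scaling, 2 with quantile normalization, 846 with array weights (214 higher, 632 lower), 1 in the fit over 14 libraries, 0 without loci under 300 bp, 0 without pre-treated grafts 7 and 9, and 0 to 1 with single libraries left out. Ggh, Ltbr and Mpst lost their calls in each of those 8 fits, and Snora3 missed the filter in the 4 without a pre-treated graft. With the mouse as a replicate block, 1 graft gene passed, and mast cell and eosinophil (0.0463) and skeletal muscle lists (0.0228) were added; the block changed no other call. Graft lists numbered 12, from 8 to 14 with single libraries left out, 4 without pre-treated grafts 7 and 9 and 0 with an estimated correlation. The culture-raised genes in grafts had p from 4.03e-19 to 1.34e-11 with single libraries left out and 0.0515 with an estimated correlation. The 2 genes that differed between models numbered 2 to 9 with single libraries left out and 1 without short loci.

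In culture the 313 genes became 13 with a log2 ratio of 2, and the 16 dose genes 9 with that ratio, 8 with a floor of 5 FPKM and 5 without short loci.

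Lists that turned direction had these camera p: in vivo, mast cell and eosinophil genes without decitabine mouse 1 (0.0178); MHC class II (0.64), neutrophil (1.02e-04), endothelial (0.898) and islet genes (0.16) without decitabine mouse 3; macrophage (0.0112), fibroblast (0.686), endothelial (0.219), ductal (0.00335) and mesenchymal transition genes (0.00664) without PBS mouse 4; erythroid genes without PBS mouse 5 and decitabine mouse 2 (1.65e-05). With single libraries left out, the camera p of the in vivo lists among these ran from 0.00669 to 0.637 for mast cell and eosinophil genes, from 1.07e-09 to 0.64 for MHC class II, 5.72e-06 to 0.214 for macrophage, 1.06e-08 to 0.947 for neutrophil, 4.19e-12 to 0.686 for fibroblast, 1.43e-05 to 0.898 for endothelial, 3.74e-06 to 0.779 for ductal, 4.68e-08 to 0.243 for islet and 7.25e-04 to 0.94 for mesenchymal transition genes. In grafts without pre-treated grafts 7 and 9 they were T cell (0.974), neutrophil (0.614) and ductal genes (0.00201). Uncalled lists that were called in the other direction were counted as turned only after their values were seen. Of the other list values 780 kept their side of the threshold, 51 came to pass and 89 ceased to. Of named gene values 4761 kept it, 36 came to pass, 42 ceased to and 0 turned. Depth was known only as a ratio, so no limit of detection was computed.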

Other observations

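Besides Igf2bp3 and Stbd1, the genes lower in decitabine tumours with the smallest unadjusted p by limma were Rgs13, Cacybp, Ms4a4b and Ccr7, and none passed (adjusted p = 0.999 for each of the 4). Cacybp, a calcyclin-binding protein, stood at 29.2 ± 5.37 FPKM (SD, n = 3) against 52.3 ± 5.36 in PBS tumours. Ccr7, the receptor that guides T cells and dendritic cells to lymph nodes, stood at 3.61 ± 0.911 against 6.997 ± 0.614. Ms4a4b, a T cell membrane protein, stood at 3.21 ± 0.963 against 7.57 ± 0.511, and Rgs13, a regulator of G protein signalling in B cells, at 0.152 ± 0.0624 against 1.14 ± 0.0302. In cultured cells Hells, a chromatin remodeller needed for DNA methylation, went from 11.9 to 32.6 and 31.0 FPKM, and the methylation machinery list as a whole lay at the percentiles 91.6 and 93.3.

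The test of germline genes in vivo was chosen only after the values of Dazl had been seen, and the condition that it hold without Dazl was added after the first p but before its own value was seen. A hypothesis is that germline genes, which promoter methylation keeps silent in somatic tissue, may be derepressed at low level in tumours of treated mice. Of 41 germline list members with a mean under 1 FPKM over the 6 in vivo tumours and at least 0.001 FPKM in 1 of them, 6 stood higher in all 3 decitabine tumours than in all 3 PBS tumours (14.6%), against 304 of 6118 other genes chosen by the same rule (4.97%; chance gives 5%). Fisher's exact test gave p = 0.0157, and p = 0.0481 without Dazl (5 of 40), treating genes as independent. Dazl stood at 0.0983, 0.206 and 1.15 FPKM in the decitabine tumours and at 0.0174 to 0.0441 in the PBS tumours, and Tex19.1 at 0.0402, 0.239 and 1.38 against at most 0.0309. Of the others, Sohlh2 reached 0.534 FPKM in 1 decitabine tumour. Sohlh1 (at most 0.0249) and Mov10l1 (at most 0.017) stood at 0 in the PBS tumours. Tex11 was separated narrowly, with a lowest decitabine value of 0.049 against a highest PBS value of 0.0469. A further member was separated the other way (1 in all). No other of the 20 arrangements of the 6 tumours separated as many (highest other 4), and 1 of 20 is the smallest share possible. Most of these values lie close to 0. In the grafts Dazl averaged 0.0192 FPKM with pre-treatment and 0.0226 without, and in culture it stood at 0.012, 0.111 and 0.211.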
